A study of Mus musculus with 15 samples.

How the data were processed

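RNA was taken from primary mouse cultures, 7 of OPCs and 8 of OLs, and made into polyA libraries by the Smart-seq2 protocol, which copies full-length cDNA and does not mark strand, per the labels' protocols. Groups follow the sample titles. For the SRF-KO OLs the treatment tag names a Cre lentivirus but ends in "control", and the series design text speaks of mesenchymal stem cells and Olig2-Cre, which the sample labels do not. Srf had 2.06 to 4.34 CPM in these 4 libraries and 7.13 to 9.34 in the control OLs, below every control, as the titles imply. Libraries were sequenced as single reads of 63 bases on a NextSeq550, per the labels' protocols. The authors converted and aligned reads and estimated gene abundance with bcl2fastq, STAR and RSEM, per the submitters' processing notes, which give no versions. Those notes name the builds GRCm38 and Rnor_6.0 without saying which applies to which sample, and all gene IDs in the files are mouse. Each deposited file is an RSEM gene table with length, effective length, expected count, TPM and FPKM for 45706 genes. The expected count is the authors' RSEM estimate of how many reads came from a gene, with reads that match several genes shared out, so 8.33% to 9.78% of the values in an OPC file and 24.3% to 33.9% in an OL file, zeros included, lie more than 1e-06 from a whole number. The TPM values in the deposited files are those counts divided by effective length and scaled to a fixed total. The deposited FPKM values were not used, since they carry the same information as TPM. Symbols came from the reference gene table for 45143 of the IDs, and coordinates from GENCODE M21 on GRCm38.

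Both kinds of file were checked against that annotation. Among 12274 genes with a single annotated transcript and at least 1 intron, the listed length equalled the spliced transcript length in 73.7% of cases in every OPC file and in 0% in the OL files. It equalled the genomic span, introns included, in 73.9% of cases in every OL file and in 0% in the OPC files. Equality means the same whole number of bases. From these lengths it is inferred that the OL counts include reads from introns and from anything else inside a gene body, so TPM is not comparable between the stages, and a comparison of OLs with OPCs compares quantification methods as well as cells. Comparisons within a stage use 1 method. The median of length minus effective length was 210 to 271 bases in OPC files and 69.6 to 72.8 in OL files. Overlapping genes and near-identical copies cannot be told apart in unstranded gene-body counts, so values of genes such as Trim30a, Pcdhga3 and Hist1h2ao are uncertain.

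Expected counts were rounded and tested with edgeR 4.0.16 in R 4.3.3: filterByExpr on low counts, TMM scaling, quasi-likelihood fits and F-tests, and Benjamini-Hochberg adjustment at 0.05. Each knockout comparison used the libraries of its stage, the stage comparison the control libraries, and the interaction all 15. The 28 gene lists hold 731 members, of which 729 matched the files, and were fixed before the data were examined, as were the designs, the rule for named genes and all alternatives except those said to be added later. They cover SRF-MRTF and immediate-early targets, actin, focal adhesion, tubulin, YAP-TEAD, oligodendrocyte stages, cell cycle, p53, senescence, interferon, lipid synthesis, stress, matrix, other cell types, mitochondrial, nuclear-retained and sex-linked genes. A list with at least 3 tested members was tested with camera in limma 3.58.1 on voom values, which compares a list with all other genes. Its inter-gene correlation was preset at 0.01, with an estimated correlation and fry as alternatives. List medians are of voom fold changes and single genes are edgeR estimates with its default prior count. The SE given with an edgeR estimate is its absolute log2 fold change divided by the square root of the F statistic. It is thus derived from the test and is not a separate measure of spread. A prior count of 2 entered the log2 CPM levels of libraries. The genes named are Srf, the 6 largest rises and falls with average log2 CPM of at least 3 and no overlap in TPM between groups, and from each list the 2 members with the smallest p (1 for lists of other cell types and of mitochondrial, nuclear-retained or sex-linked genes), all among genes with adjusted p under 0.05. Gene models without a proper name were skipped among the largest changes. A list without such a member may give its most abundant one. For the stage comparison the 5 largest changes each way and 2 members of 4 lists were named, and for the interaction the 6 smallest p at that level. Others are said to be chosen after their values were seen.

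Tests were run on simulated counts with 100 genes changed by a log2 of 1 and 100 by a log2 of 2. The changed genes were drawn from those with higher counts, and genes were simulated independently of each other. No trend with transcript length and no outlying library was simulated, so recovery and false calls may differ in the real data. edgeR recovered 76 and 97 of these with 15 false calls in the OPC design (13037 genes), 70 and 97 with 7 false calls in the OL design (14974 genes), 45 and 86 with 3 for the interaction (15366 genes) and 83 and 97 with 9 for the stages (14604 genes). DESeq2 1.42.0 recovered 82 and 97 with 35 false calls in the OPC design (13271 genes) and 80 and 97 with 29 in the OL design (15193 genes). CPM was computed from the deposited expected counts with TMM factors. The exception is the ratio of control OL to control OPC CPM of the genes lower in SRF-KO OLs and their random sets. It used library totals, with 0.5 CPM added to each group mean. For Srf an exact permutation test was run on log2(TPM + 1). A gene at 0 in a group was given a floor of 3 counts over that group. Exact Clopper-Pearson intervals at 95% were given for ratios of pooled counts.

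The alternatives were RLE size factors, library totals, DESeq2, limma-voom, no filter (at least 1 count) or a stricter filter (at least 1 CPM and 10 counts), limma on log2(TPM + 1) or log2(TPM + 0.1), an effective length offset, robust empirical Bayes, all 4 groups in 1 fit, the replicate number as a block, a threshold of 0.01 for genes changed in both stages, and each library left out in turn. Added after the data were seen were fits without SRF-KO OL replicate 4 under other settings, a stage comparison limited to genes whose listed lengths differ by no more than a factor of 1.1, and removal of each library's trend with transcript length. That trend was the local regression, with a span of 0.3, of a gene's log2 level relative to its mean on its spliced length, and it entered the edgeR offset.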

Results

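The study measured polyA RNA in cultures of mouse brain cells whose Srf gene could be removed. SRF (serum response factor) is a transcription factor that works with MRTF cofactors on genes of the actin cytoskeleton and with other cofactors on immediate-early genes. Oligodendrocyte precursor cells (OPCs) are the dividing cells that give rise to oligodendrocytes (OLs), the cells that make myelin. OPCs were purified by immunopanning, which captures cells on antibody-coated dishes, from mice whose Srf alleles carry sites for the Cre recombinase. Cre removed Srf in dividing OPCs through an adeno-associated virus (AAV), with a virus carrying a deleted Cre as control, and the cells were frozen 48 hours after infection. In the other cultures a lentivirus carrying Cre and GFP, or GFP alone as control, was added on day 6, and the cells were frozen on day 3 of differentiation. There were 4 control OPC, 3 SRF-KO OPC, 4 control OL and 4 SRF-KO OL libraries, 15 in all. Total expected counts per library ran from 8964310 to 16026511 in control OPCs, 9074812 to 15125229 in SRF-KO OPCs, 7188698 to 13139258 in control OLs and 4303739 to 11721394 in SRF-KO OLs. Mitochondrially encoded genes took 4.65% to 5.73% of counts in the OPC libraries and 9.08% to 14.2% in the OL libraries, the highest in SRF-KO OL replicate 4. Values below are normalised CPM (counts scaled to a common library size with TMM factors), as mean ± SD over libraries, and log2 fold changes are knockout over control unless stated.

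Srf (ENSMUSG00000015605, protein-coding, GRCm38 chromosome 17, 46548329 to 46556175, minus strand) was nearly lost in SRF-KO OPCs and partly lost in SRF-KO OLs. In OPCs it had 7.87 ± 1.71 CPM in controls (SD, n = 4) and 0.21 ± 0.013 in knockouts (SD, n = 3), with 88 to 106 counts per control library and 2 to 3 per knockout library. The pooled counts, 379 against 7, put the knockout at 2.74% of control (95% Clopper-Pearson interval 1.09% to 5.70%). In OLs it had 8.29 ± 0.97 CPM in controls and 3.04 ± 0.96 in knockouts (SD, n = 4 each), and the pooled counts of 348 and 103 gave 36.9% of control (95% interval 29.3% to 46.1%). Intervals of this kind cover counting error only. The log2 fold change was -5.16 (SE 0.40) in OPCs and -1.45 (SE 0.22) in OLs, with Benjamini-Hochberg adjusted p of 0.000569 and 0.0224 in edgeR's quasi-likelihood test. Every knockout library lay below every control library of its stage, and the two-sided exact permutation p was 0.0286 in each stage, the smallest that either design allows. Srf kept its edgeR call in OPCs without any 1 of the 7 libraries (adjusted p up to 0.00937). In OLs it kept it without control OL replicate 4 (0.0273) or SRF-KO OL replicate 4 (0.00246) and lost it without control OL replicates 1 (0.104), 2 (0.0830) or 3 (0.0946) or SRF-KO OL replicates 1 (0.0724), 2 (0.0951) or 3 (0.104). The OPC files count spliced transcripts, and the labels do not say which exon Cre removes, so a shortened transcript from the deleted allele would still be counted. By their listed lengths the OL files count the whole gene body, so reads from introns may be part of the OL remainder. The percentages of the stages are thus not on the same measure.

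**Figure D1:**
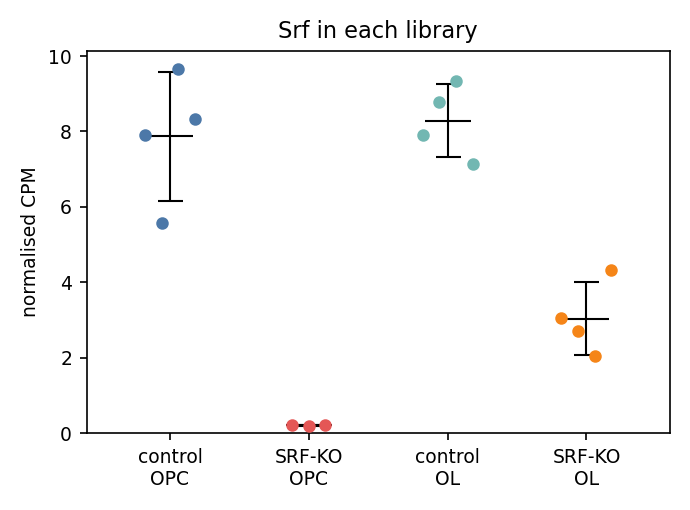
Normalised CPM of Srf (vertical axis) in each of the 15 libraries, by group (horizontal axis). Points are libraries, the black line is the group mean and the bars are 1 SD. SRF-KO OPCs average 0.21 CPM against 7.87 in their controls, and SRF-KO OLs average 3.04 against 8.29.

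The comparison of SRF-KO with control OPCs asks which transcripts differ after Cre removes Srf in dividing precursors. No library of either stage came from Cre-treated cells without floxed alleles. Effects of Cre itself were thus not separated from loss of SRF for any gene or list. The SRF-MRTF and immediate-early lists fell and the p53 target list rose in camera, and of the 3 only the p53 list kept its call with an estimated correlation (adjusted p = 0.0425, against 0.0697 for each of the other 2). In fry, the other alternative, all 3 were called (adjusted p = 0.00183 for p53, 0.00718 for SRF-MRTF and 0.00216 for immediate-early genes). Egr1 (chromosome 18, 34859823 to 34864984), an immediate-early transcription factor and known SRF target, went from 269 ± 10.9 to 167 ± 9.99 CPM (SD, n = 4 and 3), a log2 change of -0.69 (SE 0.080, edgeR adjusted p = 0.0152). Lima1 (chromosome 15, 99778470 to 99875456), which encodes an actin-binding LIM-domain protein and belongs to the SRF-MRTF list, went from 117 ± 6.82 to 74.4 ± 3.49 CPM, a log2 change of -0.65 (SE 0.087, edgeR adjusted p = 0.0300). Dcxr (chromosome 11, 120725399 to 120727281), a carbonyl reductase on the p53 target list, rose from 34.0 ± 3.4 to 58.1 ± 4.52 CPM, a log2 change of 0.77 (SE 0.11, edgeR adjusted p = 0.0342). Mxd4 (chromosome 5, 34173883 to 34187720), a MYC-network repressor, rose by 0.79 on the log2 scale (SE 0.095), and Ckmt1 (chromosome 2, 121357714 to 121363737), a mitochondrial creatine kinase, rose by 0.74 (SE 0.11).

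Of 13271 genes tested, 9 passed an edgeR adjusted p of 0.05, 3 higher and 6 lower. The split was 64 and 59 in DESeq2 and 6 and 7 with library totals, so these counts do not settle which direction prevails. The 6 lower genes were Srf, Egr1, Lima1, Gtf3c4 (-0.67, SE 0.092), a subunit of a polymerase III transcription factor, Ptges3l (-1.97) and Gm26917 (-0.79). At an unadjusted p under 0.05 there were 1579 genes, 11.9% of those tested. The next genes were Gem, a small GTPase, at 1.57 (adjusted p = 0.0532), and Egr2, an immediate-early gene, at -1.66 (adjusted p = 0.0559), neither of which passed edgeR's adjusted threshold. Ptges3l, Gm26917, Gem and Egr2 were named after their values were seen.

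The p53 target list, genes that p53 switches on after DNA damage, rose as a group in SRF-KO OPCs: the median log2 change of its 33 tested members was 0.31, 28 were positive, and the camera adjusted p was 5.85e-11. Dcxr passed over all genes tested, while 16 members were higher when adjusted over the list alone. It was the only list of the 27 tested that also passed with an estimated correlation (adjusted p = 0.0425 with an estimated correlation). Ccng1, a p53-induced cyclin, had 816 ± 70.8 CPM in controls and 1030 ± 14.5 in knockouts (log2 0.34, edgeR adjusted p = 0.194). Two-sided list tests were used throughout, and "adjusted over the list alone" means Benjamini-Hochberg adjustment of edgeR's p over the members only.

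The SRF-MRTF target list, mostly actin and actin-binding genes, fell in SRF-KO OPCs (median -0.22 over 23 members, 17 negative, camera adjusted p = 0.000155; adjusted p = 0.0697 with an estimated correlation). Lima1 was the member lower over all genes tested, and 6 were lower when adjusted over the list alone. Actb, cytoplasmic actin, had 3946 ± 241 CPM in controls and 2983 ± 419 in knockouts (log2 -0.40, edgeR adjusted p = 0.187). The immediate-early list fell (median -0.13 over 24 members, camera adjusted p = 0.00189; adjusted p = 0.0697 with an estimated correlation), with Egr1 lower over all genes and 8 lower and 3 higher when adjusted over the list alone. Smaller shifts of the same direction were called for actomyosin contraction (median -0.06, camera adjusted p = 0.0304), focal adhesion and integrins (-0.08, 0.0243) and the Arp2/3 complex (-0.06, 0.0499), each with adjusted p = 0.284 with an estimated correlation. The actomyosin list (Lima1 and Cnn2 among others) and the focal adhesion list (Vcl and Zyx among others) share members with the SRF-MRTF list. Their calls are thus not independent of it. The list of 44 tested actin filament assembly and turnover genes was not called (median -0.03, camera adjusted p = 0.401).

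Lists of cell identity and metabolism also moved in SRF-KO OPCs, none of them past the threshold with an estimated correlation. In fry the astrocyte, mitochondrial, myelin, interferon and integrated stress response lists were called (adjusted p from 0.00183 to 0.0186). The cell cycle, OPC, cholesterol and fatty acid lists were not called in fry. SRF-KO OPC replicate 2 stood apart from the other 6 OPC libraries, at 47.6 on the first principal component (27.3% of variance) against -23 to 6.01. Astrocyte genes rose (median 0.24 over 18 members, camera adjusted p = 0.000165; adjusted p = 0.0650 with an estimated correlation), with 9 higher and 1 lower when adjusted over the list alone and medians of 0.28, 0.41 and 0.14 in SRF-KO OPC replicates 1 to 3. The 13 mitochondrially encoded genes rose (0.20, 0.000155; adjusted p = 0.0650 with an estimated correlation; median 0.08 with the length trend removed), as did myelin genes (0.13 over 20 members, 0.00360; adjusted p = 0.0697 with an estimated correlation) and interferon response genes (0.37 over 21 members, 20 positive, 0.00217; adjusted p = 0.134 with an estimated correlation). Cell cycle genes fell (median -0.07, 35 of 40 negative, camera adjusted p = 0.000940; adjusted p = 0.284 with an estimated correlation), with medians of -0.13, -0.01 and -0.11 in SRF-KO OPC replicates 1 to 3 against -0.02 to 0.04 in the control libraries, so replicate 2 lay among the controls. OPC genes (-0.10, 0.00800), cholesterol synthesis (-0.07, 0.00247) and fatty acid and sphingolipid synthesis (-0.11, 0.00389) fell with adjusted p = 0.284 with an estimated correlation, and integrated stress response genes fell (-0.14, 0.00247) with adjusted p = 0.0697 with an estimated correlation. In SRF-KO OPC replicates 1 to 3 the OPC list lay at -0.07, -0.27 and -0.03, the fatty acid list at -0.05, -0.22 and -0.06 against -0.09 to 0.06 in the controls, and the cholesterol list at -0.08, -0.02 and -0.15 against -0.06 to 0.04, so the fatty acid list left the control range in replicate 2 only and the cholesterol list in replicates 1 and 3. The other 12 lists had camera adjusted p from 0.13 to 0.994. These were tubulins, YAP-TEAD targets, newly formed oligodendrocyte, senescence, endoplasmic reticulum chaperone, extracellular matrix, neuron, endothelial, fibroblast and mural, nuclear-retained and sex-linked genes and the actin filament list above. edgeR called 1 gene without control OPC replicate 1, 2 or 4 or SRF-KO OPC replicate 3, 2 without control OPC replicate 3 or SRF-KO OPC replicate 1, and 4 without SRF-KO OPC replicate 2, with Srf among them each time. Egr1 was called in 2 of these 7 fits, Mxd4 in 1 and Lima1, Dcxr, Ckmt1 and Gtf3c4 in 0, with adjusted p of 0.0655 to 0.122 for Lima1. Without SRF-KO OPC replicate 2 the interferon (adjusted p = 0.0547), OPC (0.191) and focal adhesion (0.359) lists were lost in camera, and without SRF-KO OPC replicate 3 the cholesterol list was lost (0.0587). The focal adhesion list was also lost without control OPC replicate 4 (0.0816), and the actomyosin list without control OPC replicates 1 (0.123) or 2 (0.0552) or SRF-KO OPC replicate 1 (0.115). The Arp2/3 list kept its call only without control OPC replicate 4 (0.0456) or SRF-KO OPC replicate 2 (0.000704). Nuclear-retained genes, not called with all libraries, were called without SRF-KO OPC replicate 3 (0.0452).

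**Figure D2:**
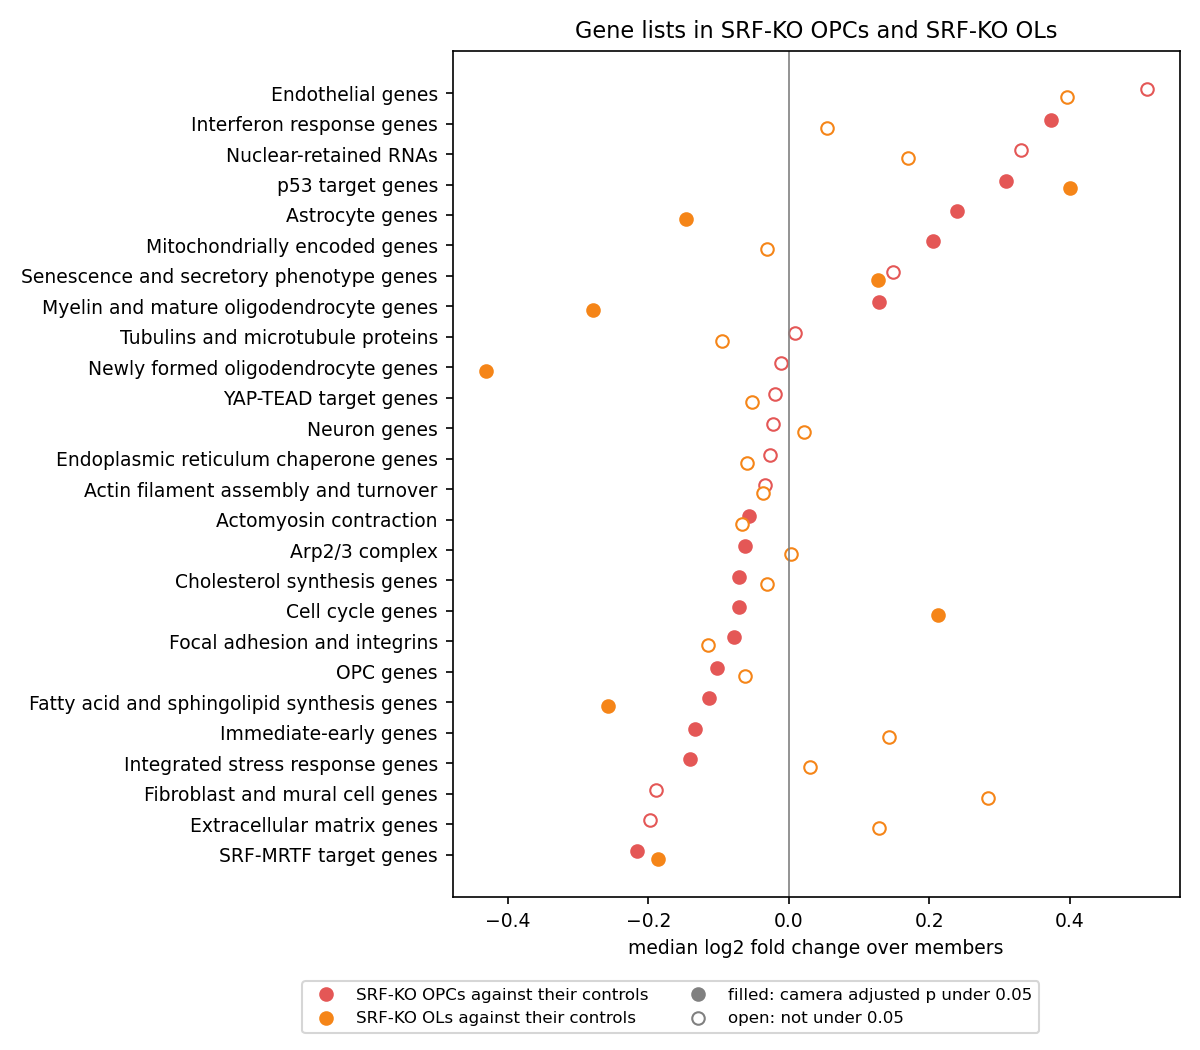
Median log2 fold change over the tested members of each gene list (horizontal axis), knockout over control, in OPCs (red) and OLs (orange). Filled points have a camera adjusted p under 0.05 and open points do not. The p53 list lies at 0.31 in OPCs and 0.40 in OLs, the SRF-MRTF list at -0.22 and -0.19, and the newly formed oligodendrocyte list at -0.01 and -0.43.

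The comparison of SRF-KO with control OLs asks the same of differentiating cells, and here too Cre itself was not separated from loss of SRF. Lbp (chromosome 2), which encodes a lipopolysaccharide-binding protein, rose from 4.31 ± 0.76 to 15.5 ± 2.69 CPM (SD, n = 4 each), a log2 change of 1.84 (SE 0.19, edgeR adjusted p = 0.00453). Mmp2 (chromosome 8), a matrix metalloproteinase, rose from 1.65 ± 0.58 to 9.82 ± 2.26 CPM, a log2 change of 2.57 (SE 0.27, edgeR adjusted p = 0.00463). Opalin, a membrane protein of mature oligodendrocytes, went from 14.1 ± 1.78 to 5.59 ± 1.82 CPM, a log2 change of -1.37 (SE 0.21, edgeR adjusted p = 0.0228). Matn4, a matrix protein on the OPC list, went from 35.9 ± 4.3 to 19.8 ± 1.87 CPM, a log2 change of -0.85 (SE 0.14, edgeR adjusted p = 0.0250). Pqlc3, a PQ-loop membrane protein, rose by 1.08 (SE 0.14) and Ppic, a cyclophilin, by 1.06 (SE 0.17) on the log2 scale.

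**Figure D3:**
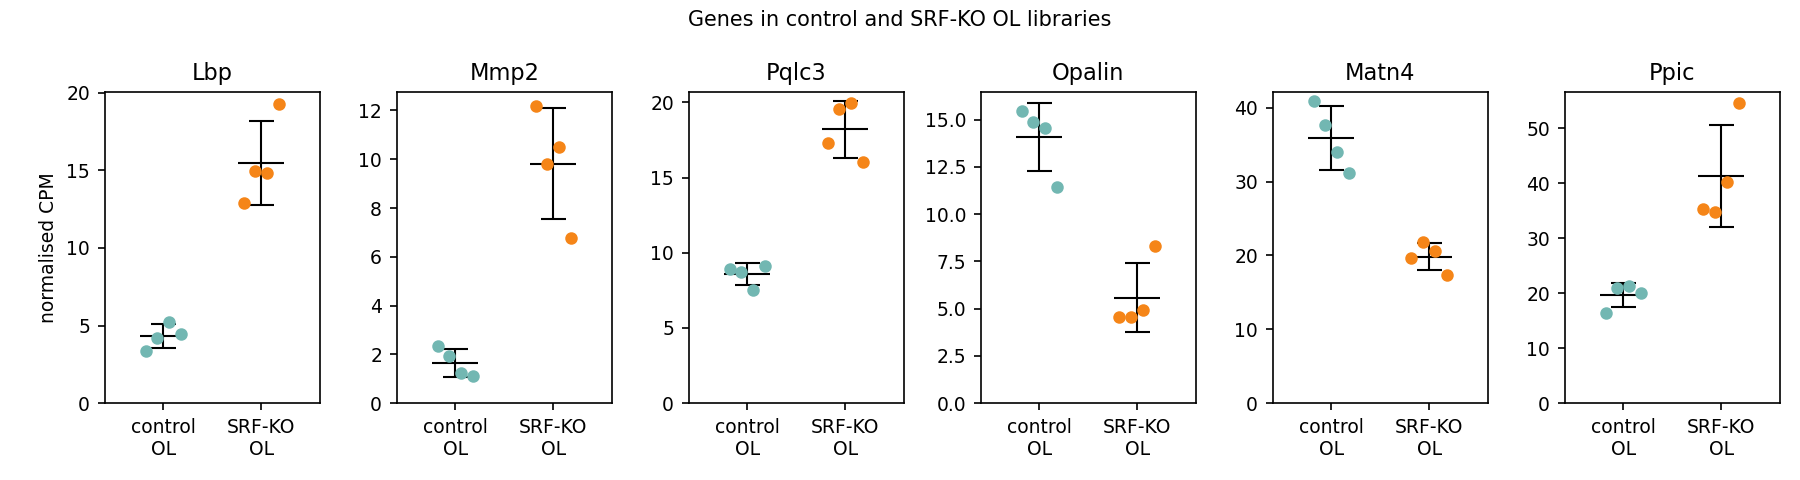
Normalised CPM (vertical axes, each from 0) of 6 genes in the 4 control OL and 4 SRF-KO OL libraries (horizontal axes). Points are libraries, the black line is the group mean and the bars are 1 SD. Mmp2 averages 1.65 CPM in control OLs and 9.82 in SRF-KO OLs, and Opalin 14.1 and 5.59.

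Of 15193 genes tested, 45 passed the edgeR adjusted threshold, 10 higher and 35 lower, and 1757 passed at an unadjusted p under 0.05. The excess of lower genes depends on the scaling, since library totals gave 39 higher and 35 lower. Steep falls were in Cdk8 (-2.63, SE 0.39), Itga9 (-2.57, SE 0.35), Dnah7b (-2.38, SE 0.36) and Trim30a (-2.37, SE 0.31). By their listed lengths the OL files count reads over whole gene bodies, introns included, and 27 of the 35 lower genes have introns in the gene body that was counted. In control OLs those 27 had a median log2 ratio of 4.16 to their CPM in control OPCs, whose files count exons only. For this ratio CPM was scaled by library totals, with 0.5 CPM added to each group mean.

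Newly formed oligodendrocyte genes, which mark cells that have just left the precursor state, fell as a group in SRF-KO OLs (median -0.43 over 27 members, 24 negative, camera adjusted p = 3.56e-12; adjusted p = 0.227 with an estimated correlation). None passed over all genes tested, and 16 were lower when adjusted over the list alone. Bcas1 had 1859 ± 419 CPM in controls and 1052 ± 84.4 in knockouts (log2 -0.82, edgeR adjusted p = 0.154). Myelin genes fell (median -0.28 over 32 members, 26 negative, camera adjusted p = 4.13e-06; adjusted p = 0.330 with an estimated correlation), with Opalin lower over all genes tested and 11 lower and 2 higher when adjusted over the list alone. The groups overlapped, with control OL replicate 4 at -0.237 and SRF-KO OL replicate 2 at -0.232. The p53 list rose here too (median 0.40 over 31 members, 25 positive, camera adjusted p = 1.67e-06; adjusted p = 0.227 with an estimated correlation), with 0 over all genes tested and 11 higher when adjusted over the list alone. It lay at 0.28 to 0.39 in SRF-KO OL replicates 1 to 3 and at 0.09 in replicate 4, inside the control range of -0.11 to 0.09. Cell cycle genes rose (median 0.21, 38 of 40 positive, camera adjusted p = 2.70e-06; adjusted p = 0.227 with an estimated correlation), with 0 members past either adjustment and 0.07 in SRF-KO OL replicate 4, below control OL replicate 2 (0.09).

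The SRF-MRTF list fell in SRF-KO OLs (median -0.19 over 26 members, 20 negative, camera adjusted p = 0.0358; adjusted p = 0.345 with an estimated correlation), with 0 members over all genes tested and 3 lower and 1 higher when adjusted over the list alone. Actb had 7766 ± 2034 CPM in controls and 3557 ± 971 in knockouts (log2 -1.13, edgeR adjusted p = 0.154). Fatty acid and sphingolipid synthesis genes were called lower (-0.26, camera adjusted p = 0.00932; adjusted p = 0.544 with an estimated correlation), but the median was -0.03 without SRF-KO OL replicate 4, which lay at -0.54 against -0.10 to 0.03 in the other 3 knockout libraries. Senescence genes rose (0.13, 0.0305; adjusted p = 0.330 with an estimated correlation) and astrocyte genes fell (-0.15, 0.0422; adjusted p = 0.428 with an estimated correlation). Of the knockout libraries, replicate 1 lay inside the control range for senescence genes (0.05, controls -0.07 to 0.12) and replicates 2 and 3 for astrocyte genes (-0.13 and -0.11, controls -0.16 to 0.11). Gfap, the astrocyte filament protein, had 18740 ± 6748 CPM in controls and 7486 ± 1928 in knockouts (log2 -1.32, edgeR adjusted p = 0.125). The other 19 of 27 lists were not called (camera adjusted p from 0.0687 to 0.994). They held the immediate-early, Arp2/3, actin filament, actomyosin, focal adhesion, tubulin, YAP-TEAD, OPC, interferon, cholesterol, integrated stress response, chaperone, extracellular matrix, microglia, neuron, endothelial, fibroblast and mural, mitochondrial and nuclear-retained genes.

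SRF-KO OL replicate 4 stood apart from the other 7 OL libraries, at 80.5 on the first principal component (40.5% of variance) against -18.8 to 0.448, and without it edgeR called 636 genes, all 45 among them, 231 higher and 405 lower. Without it 10 of the 31 p53 targets, 10 newly formed oligodendrocyte genes and 4 SRF-MRTF targets passed over all genes tested in the direction of their lists, with 1 gene of each of the latter lists the other way. The count was 14 without control OL replicate 1, 8 without control OL replicate 2, 8 without replicate 3, 71 without replicate 4, 7 without SRF-KO OL replicate 2 and 8 without SRF-KO OL replicate 3. The SRF-MRTF call was lost in camera without control OL replicate 2 (adjusted p = 0.0815), control OL replicate 3 (0.0691) or SRF-KO OL replicate 1 (0.191), and the fatty acid call without SRF-KO OL replicate 4 (0.226). The senescence call held without control OL replicate 2 (0.0336) or SRF-KO OL replicate 4 (0.0407) and was lost without any 1 of the other 6 libraries (0.0709 to 0.144). The astrocyte call held without control OL replicate 4 (0.00965) or SRF-KO OL replicate 2 (0.0303) and was lost without any 1 of the other 6 (0.0561 to 0.110). Lists not called with all libraries were called in some of these fits: tubulins without control OL replicate 4 or without SRF-KO OL replicate 4 (0.00493 for the latter), mitochondrial genes without SRF-KO OL replicate 4 (0.0178), and extracellular matrix genes without control OL replicate 4 (0.0313) and fibroblast and mural genes without control OL replicate 3 (0.00955). Lbp and Mmp2 passed edgeR's adjusted threshold in all 8 fits with 1 library left out, Pqlc3 in 4, and Opalin, Matn4 and Ppic in 2. Of the steep falls, Itga9 passed in 5, Trim30a in 4, and Cdk8 and Dnah7b in 3.

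**Figure D4:**
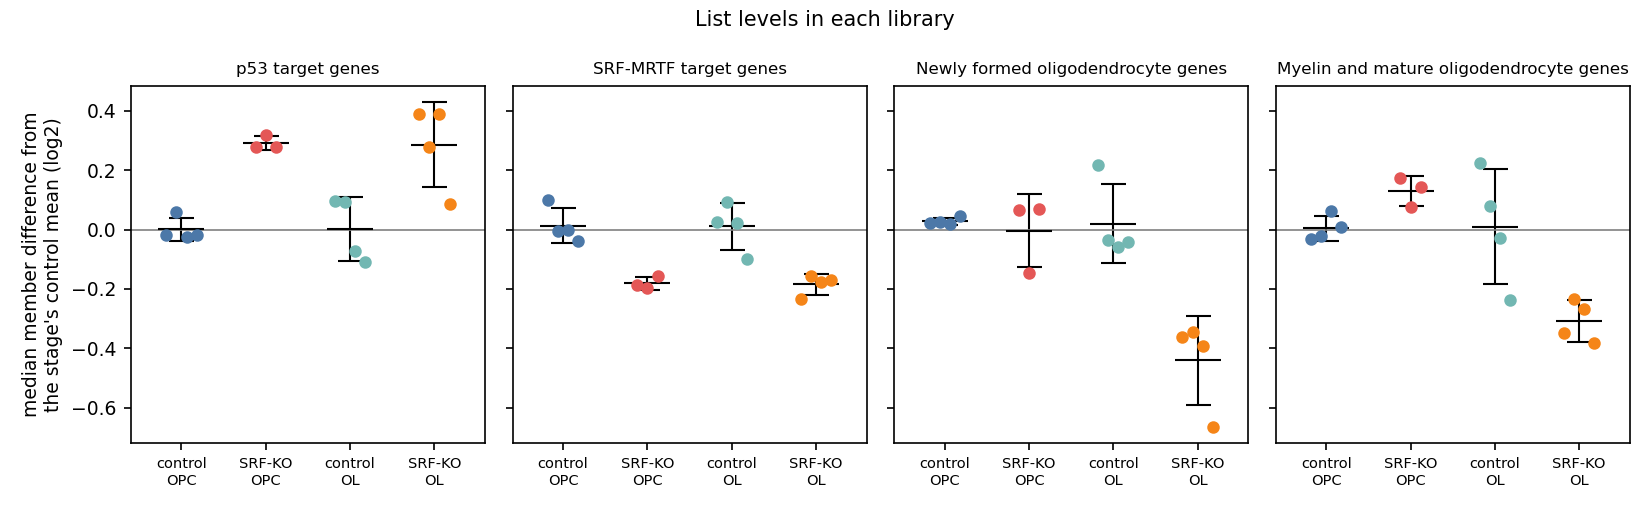
Median difference of a list's members from their mean in the control libraries of the same stage (vertical axis, log2), for 4 gene lists in each library, by group (horizontal axes). Points are libraries, the black line is the group mean and the bars are 1 SD. In the newly formed oligodendrocyte panel SRF-KO OL replicate 4 lies lowest, at -0.66.

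The difference between the knockout effects in OLs and OPCs was tested as an interaction over all 15 libraries. The arms also differ in virus, control construct and time since infection, so a difference between them is not one of stage alone. Srf itself differed by 3.68 on the log2 scale (SE 0.46, edgeR adjusted p = 0.00465), with a smaller measured fall in OLs. Mmp2 differed by 2.04 (SE 0.32, edgeR adjusted p = 0.0135), with 0.53 in OPCs against 2.57 in OLs. Serpina3n, a protease inhibitor of reactive astrocytes, differed by -1.52 (SE 0.26, edgeR adjusted p = 0.0203), with 1.02 in OPCs and -0.48 in OLs, neither passing its own test. Gtf3c4 differed by 0.94 (SE 0.16) and Tacc2, a centrosomal protein, by 1.88 (SE 0.31). Rsph3b (-2.68, SE 0.39) and Mphosph8 (-2.11, SE 0.35) differed the other way. Reads from introns, inferred from the lengths listed in the OL files, may enter the OL counts of any of the genes of this paragraph. With each of the 15 libraries left out in turn the calls of Srf and Rsph3b held in 15 fits, Mmp2 in 14, Tacc2 in 11, Mphosph8 in 10 and Gtf3c4 and Serpina3n in 9.

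In all, 18 of 16135 genes had different effects at an edgeR adjusted p of 0.05, 7 positive and 11 negative, with 1493 at an unadjusted p under 0.05. Immediate-early genes differed as a group (median 0.40, 19 of 25 positive, camera adjusted p = 1.53e-05) and kept that call with an estimated correlation (adjusted p = 0.00795 with an estimated correlation), with a median of -0.13 in SRF-KO OPCs, where the call was lost with an estimated correlation (adjusted p = 0.0697), and of 0.14 in SRF-KO OLs (15 of 22 positive), where the list was not called. Cell cycle genes (median 0.28), myelin genes (-0.47), newly formed oligodendrocyte genes (-0.32) and astrocyte genes (-0.49) were also called by camera, with adjusted p of 1.68e-08, 6.69e-07, 1.12e-05 and 1.48e-05. With an estimated correlation their adjusted p were 0.126, 0.126, 0.290 and 0.12. The p53 list (median 0.07, camera adjusted p = 0.475) and the SRF-MRTF list (0.06, 0.660) did not differ detectably between the stages. Each stage was counted by its own method, and the count was 134 without SRF-KO OL replicate 4 and 4 without SRF-KO OPC replicate 2. It was 6 without control OPC replicate 2, 7 without control OPC replicate 4, 6 without control OL replicate 1, 9 without control OL replicate 3, 42 without control OL replicate 4 and 28 without SRF-KO OL replicate 1.

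Srf was the only gene called in both knockout comparisons in the same direction among 12666 genes tested in both. It is the gene targeted in both experiments, so this overlap says nothing about other genes, and no gene was called higher in both or in opposite directions. The log2 fold changes of the stages correlated weakly across genes (Pearson r = 0.109, Spearman 0.114), and genes are not independent replicates. DESeq2 called 10 genes in both, 7 higher and 3 lower. edgeR's count was 0 without control OL replicates 1, 2 or 3 or SRF-KO OL replicates 1, 2 or 3, and 2 without SRF-KO OL replicate 4. Of the p53 list, 8 members were higher in both stages when adjusted over the list alone (Btg2, Pmaip1, Fas, Pidd1, Ak1, Aen, Eda2r and Dcxr, named after their values were seen), where independent sets of 15 and 11 among 31 would share 5.32 (Fisher's exact p = 0.0659, adjusted p of at least 0.240 over 6 list tests).

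Control OLs were compared with control OPCs to show how far the differentiated cultures had moved. Cell cycle genes fell (median -3.82, 40 of 40 lower, camera adjusted p = 4.84e-20; adjusted p = 0.0736 with an estimated correlation), for example Cdc20 from 282 ± 19.2 to 11.2 ± 0.64 CPM and Aurka from 129 ± 3.35 to 7.56 ± 0.40 (SD, n = 4 each). Myelin genes rose (median 5.61, 32 of 32 higher, camera adjusted p = 2.97e-11; adjusted p = 0.137 with an estimated correlation), with Nkx6-2 from 0.85 ± 0.17 to 61.4 ± 7.14 CPM. Mobp, a myelin protein gene with 1 count in all control OPC libraries, was 41400-fold higher in OLs with a counting interval of 7440 to 1640000. Mog, with 0 OPC counts, was at least 2580-fold higher, from a floor of 3 counts over the group. With such genes at their bounds the edgeR median of the myelin list was 5.27. Newly formed oligodendrocyte genes rose (2.42, 25 of 27 higher, camera adjusted p = 4.46e-07; adjusted p = 0.137 with an estimated correlation), including Tmem163 (0.52 ± 0.13 to 141 ± 6.43 CPM) and Enpp6 (0.090 ± 0.12 to 329 ± 23.7 CPM). OPC genes split, 16 higher and 17 lower, with Pdgfra, the PDGF receptor of precursors, falling from 496 ± 12.1 to 53.8 ± 2.25 CPM and C1ql1 rising from 9.27 ± 0.69 to 117 ± 10.4.

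The p53 list fell between the stages (median -1.59, 30 of 33 lower, camera adjusted p = 7.93e-08; adjusted p = 0.0918 with an estimated correlation). Astrocyte genes rose (3.17, 18 of 20 higher, 2.01e-05; adjusted p = 0.137 with an estimated correlation), Gfap by 8.61 on the log2 scale. YAP-TEAD targets (1.52, 0.00267), mitochondrial (1.86, 0.00369), nuclear-retained (2.30, 0.0109) and microglia genes (5.21, 0.0109) also rose, the last with an edgeR median of 7.01, or 4.66 with genes at 0 at their bounds. Among genes of nearly equal listed length the mitochondrial list had the reverse direction and was not called (camera adjusted p = 0.654). Cholesterol synthesis (-0.71, 0.000957), integrated stress response (-0.72, 0.00936) and immediate-early genes (-0.58, 0.0356) fell. These 7 lists had adjusted p of 0.0963, 0.358, 0.234, 0.137, 0.371, 0.358 and 0.175 with an estimated correlation, in that order, and the other 16 of 28 lists had camera adjusted p from 0.101 to 0.850, with fibroblast and mural genes called without control OPC replicate 4 (0.0397). The labels do not say whether OPC and OL cultures came from the same animals, so differences between animals, their sex included, were not separated from stage here or in the interaction. Each library was made from a culture. Changes in the mix of cells were thus not separated from changes within cells, here or in the knockout comparisons. The counting method differs between the stages, so folds of genes with introns mix stage and method. Il31ra and Myo3a, at least 22400-fold and 22000-fold higher with 0 OPC counts, and Trim30a, at least 2860-fold higher, are values of that kind. So are Lpin2, Pcdhga11 and Pcdhga3, at least 449-fold, 259-fold and 232-fold lower with 0 OL counts. Hist1h2ao, at least 231-fold lower with 0 OL counts, is uncertain because near-identical copies cannot be told apart. Gemin4, with 1 OL count, was 2080-fold lower (interval 373 to 82200). edgeR called 11970 of 15027 genes (6390 higher, 5580 lower). Scaling by library totals moved the split to 5119 and 6843, and limma on log2(TPM + 1) to 2415 and 9895. Among genes of nearly equal listed length in both kinds of file, 1555 of 1752 were called, 941 higher and 614 lower.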

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

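The tests of gene-body reads, of SRF-KO OL replicate 4 as the single source of the lower genes, of exchanged labels, of Cre itself and of the length trend removed were chosen after the results they bear on were seen.

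In SRF-KO OLs 35 genes were lower, 25 of the 27 with introns more than 3 log2 units above their OPC level in control OLs. Those 27 had a median log2 ratio of control OL to control OPC CPM of 4.16, against 0.420 at the 95th percentile of 10000 random sets matched on OL level, which fits reads from outside annotated exons, though mRNAs that rise with differentiation would also raise the ratio. SRF-KO OL replicate 4 is not their source, since all 35 stayed called without it. Within groups the mean level of the 27 genes with introns was correlated with the ribosomal gene CT010467.1 over 8 libraries. Pearson r was 0.654 (permutation p = 0.0859) and Spearman rho 0.595 (permutation p = 0.132, both 0.132 after adjustment). Without the 2 libraries farthest from the median r was 0.0238, so ribosomal carry-over stays open for these 27. The lower genes without introns were not in that correlation. Among the 35 are RNAs that carry no polyA tail, Rn7s1 and Rn7s2 (both -2.07, adjusted p = 0.0109) and Rn7sk (-1.47, 0.0228), as well as mt-Ts1 (-2.45) and Mir6236 (-6.68), which would go with a carry-over of such RNA. The 35 genes took 2.81% of control OL and 0.833% of SRF-KO OL counts. For the 25 genes above, a candidate explanation is that RNA from inside their introns differs between the groups, rather than the mRNAs the genes are named for. It does not account for the genes without introns or for Srf, which had 8.29 CPM in control OLs and 7.87 in control OPCs.

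SRF-KO OL replicate 4 differed from the rest of its group. Its Srf level of 4.34 CPM lies below the lowest control OL library (7.13) and control OL replicate 4 (7.13) lies above every knockout, which argues against exchanged labels. Its deviation from the other 3 SRF-KO OL libraries fell with spliced length (Spearman rho = -0.451 across 15193 genes), but control OL replicate 2 showed as strong a trend within its group (-0.456), so a loss of long transcripts special to it cannot be told apart from a trend that runs through the OL libraries. With that trend removed its root mean square deviation was still 0.563 (log2) against 0.199 to 0.319 in the other 7 OL libraries, so length is not the whole difference. A lower share of oligodendrocytes would raise the markers of other cells, but these went both ways, with the astrocyte list at a median of -0.346 (13 of 20 members below), the fibroblast and mural list at -0.01, the microglia list at 0.10 and the neuron list at 0.31 (5 of 16 below). The newly formed oligodendrocyte list lay at -0.31 (20 of 27 below) and the myelin list at 0.06, and mitochondrial genes were 0.66 higher (13 of 13).

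The p53 target list was higher in SRF-KO OPCs, with a median of 0.31. At the preset correlation it does not rest on 1 library, since the highest camera adjusted p with 1 of the 7 left out was 6.33e-08. With an estimated correlation its camera adjusted p was 0.0425 over all 7, and leaving out libraries was not run at that setting. A general shift of short or abundant genes is argued against, since 0 percent of 10000 random lists matched on level and spliced length reached it and the highest reached 0.121. Whether Cre recombinase itself, which can cut DNA, rather than loss of SRF lies behind the rise cannot be told apart, because 0 libraries come from Cre-treated cells without floxed alleles. A response to the loss of SRF is thus 1 possible explanation and was not tested separately.

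Other groupings of the same libraries were fitted to see whether chance can be excluded. In OPCs 1 of 35 splits, the real one, gave as many genes (9, against 1 in the highest other). For the stages 1 of 35 did (11970 against 0). Each of the other stage splits mixes OPC and OL libraries within a group, which widens the spread there, so this result could hardly have come out otherwise. For the interaction 1 of 100 drawn splits did, by a narrow margin (18 against 15). The draw with 15 labelled control OL replicates 1 to 4 as knockouts and mixed the OPC labels. It kept the OL grouping with its sign reversed, so these draws cannot decide whether the count reflects an interaction. For the OPC count the share of 1 of 35 is under 0.05 and is the smallest possible. Srf, the deleted gene, is among the 9, and the other splits mix knockout and control libraries within a group. This share thus does not exclude chance for the other genes called. The OPC count fell to 1 to 4 with 1 library left out. The interaction count fell to 0 with the replicate number as a block. In OLs 2 of 35 splits gave 45 or more genes, so chance could not be excluded from the count alone. The other split called 453 genes, 1 of them among the 45, with control OL replicate 4 beside SRF-KO OL replicates 1 to 3. It points to a structure of the samples, and its fold changes followed spliced length (rho = 0.455 across genes). With each library's length trend removed the real split called 166 genes and the highest of the 34 others called 1, so 1 of 35 splits gave as many. The split above called 0, but the removal takes out the trend that it followed, so this 0 was largely built in. These fits cannot decide whether another structure of the samples lies behind the OL count.

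Of 194 sets of 4 libraries examined, 18 had 1 library far from the other 3 by Dixon's criterion, where chance gives about 1 in 20 (9.7), and 8 of the 18 were SRF-KO OL replicate 4. Groups of 3 were not examined. That library was the lowest of its group for Hmgcs1 (476 CPM), an enzyme of cholesterol synthesis, and Fyn (144), a kinase of the oligodendrocyte lineage, and the highest for Malat1 (4380), Elavl3 (112), Arpc1a (415) and Opalin (8.3). Its YAP-TEAD list lay at -0.37 and its newly formed oligodendrocyte list at -0.66, as median differences from the control mean (log2). SRF-KO OL replicate 3 stood apart for Vwf at 3.29 CPM and for the OPC list at -0.14. Control OL replicate 4 stood apart for Malat1 at 2870 CPM, and control OL replicate 3 had a total of 7.19 M counts against 12.9 M to 13.1 M in its group. Control OL replicate 1 stood apart for the newly formed oligodendrocyte list (0.22), control OL replicate 2 for the extracellular matrix (-0.17) and endothelial (0.16) lists, control OPC replicate 2 for the p53 (0.060) and astrocyte (0.046) lists and control OPC replicate 1 for the senescence list (0.031).

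The knockout effect differed between OLs and OPCs in the interaction test for Srf (3.68), Mmp2 (2.04), Tacc2 (1.88) and Gtf3c4 (0.94) in the positive direction and for Rsph3b (-2.68), Mphosph8 (-2.11) and Serpina3n (-1.52) in the negative direction, on the log2 scale. The arms also differ in virus, control construct and time since infection. Camera called 5 lists, with medians of 0.40 (immediate-early), 0.28 (cell cycle), -0.47 (myelin), -0.32 (newly formed oligodendrocyte) and -0.49 (astrocyte). With an estimated correlation the immediate-early list kept its call (adjusted p = 0.00795) and the other 4 lost it (0.126, 0.126, 0.290 and 0.12).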

How the results depend on the processing

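The removal of the length trend, the fits without SRF-KO OL replicate 4 under a second changed setting and the limit to genes of nearly equal listed length were chosen after the data were seen, and the other alternatives before. Where values moved, the cause was not tested unless stated.

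The 9 genes of the OPC comparison became 123 in DESeq2 (64 higher, 59 lower), 101 with no low-count filter, 31 with all 4 groups in 1 fit, 29 with the length trend removed (all 9 among them), 18 with robust empirical Bayes and 2 with an effective length offset. Leaving out 1 library gave 1 to 4. On simulated data DESeq2 made 35 false calls in this design and edgeR 15. Srf in OPCs kept its call in each alternative run.

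The 45 genes of the OL comparison became 288 in DESeq2, 129 with no low-count filter, 94 with all 4 groups in 1 fit, 74 with library totals (39 higher, 35 lower, against 10 and 35), 17 with an effective length offset, 6 on log2(TPM + 1) and 4 on log2(TPM + 0.1). With the length trend removed there were 166 (all 45 among them). Leaving out 1 library gave 7 to 636, the most without SRF-KO OL replicate 4, and without that library DESeq2 called 1096 and the fit with the length trend removed 1114. Srf in OLs lost its call at -0.66 on log2(TPM + 1) (adjusted p = 0.162), -1.09 on log2(TPM + 0.1) (0.192) and -1.45 with the effective length offset (0.0543), and ran from -1.62 to -1.34 with 1 library left out. Library totals moved the median of all genes to 0.24 in OLs, against 0.02 with TMM, and to -0.24 between the stages, against 0.10.

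With the replicate number as a block 2 genes were called in OPCs, 5 in OLs, 0 in the interaction (1078 at an unadjusted p under 0.05) and 0 in both stages, Srf in OLs was at -1.45 (adjusted p = 0.193), and without SRF-KO OL replicate 4 the block gave 1208 in OLs. The labels do not say that the numbers pair libraries. Libraries of the same number had deviations correlated at 0.0144, 0.049 and -0.0157 in OPCs and 0.0264, -0.239, -0.0781 and -0.281 in OLs.

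The 18 genes of the interaction became 167 in DESeq2, 88 with no low-count filter and 30 in limma-voom, with 4 to 134 when 1 library was left out. The count in both stages was 10 in DESeq2, 0 at an adjusted p under 0.01 and 0 to 2 with 1 library left out. Among genes of nearly equal listed length 1555 differed between the stages, where fewer genes (1752) were tested.

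The 15 lists called in OPCs became 1 with an estimated correlation and 8 in fry. Those in fry were p53, SRF-MRTF, immediate-early, astrocyte, mitochondrial, myelin, interferon and integrated stress response genes. The 8 called in OLs became 0 with an estimated correlation, 0 in fry, 0 with an estimated correlation and without SRF-KO OL replicate 4, and 5 to 9 with 1 library left out. The 12 called between the stages became 0 with an estimated correlation, 26 in fry and 1 among genes of nearly equal length, where 3 lists could be tested. There the mitochondrially encoded list reversed (camera adjusted p = 0.654). Of the values of single genes called, 753 kept their call and 249 lost it in the same direction, and of those of single lists 393 and 91. The single-gene counts include the stage comparison, whose named genes kept their calls in all 8 fits with 1 library left out. In the knockout comparisons most named genes lost theirs in some of these fits. The totals of 4303739 and 5133146 counts in SRF-KO OL replicates 3 and 4 limit what can be seen for low genes, Srf among them with 10.2 counts in replicate 3.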

Other observations

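The fits with the length trend removed, the genes named in this part and the overlap of list members were chosen after the results were seen.

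Several SRF-linked genes did not pass over all genes tested in SRF-KO OPCs and passed when adjusted over their list alone. Cnn2, an actin-binding calponin, had a log2 change of -1.45 (SE 0.26, edgeR adjusted p = 0.0937), Egr2 -1.66 (SE 0.26, 0.0559), Arc, an activity-regulated gene, -1.32 (SE 0.28, 0.172), and Ier2, an immediate-early gene, -0.50 (SE 0.10, 0.150). Tgfb1i1, a focal adhesion protein, had -1.10 (SE 0.21, 0.117). Among p53 targets Pmaip1, a promoter of apoptosis, had 0.87 (SE 0.14, 0.0701), Ercc5, a DNA repair nuclease, 0.60 (SE 0.11, 0.0972), and Cdkn1a, an inhibitor of the cell cycle, 0.57 (SE 0.13, 0.187). In SRF-KO OLs, likewise past the threshold over their lists alone, the oligodendrocyte transcription factors Myrf, Sox10 and Tcf7l2 had -0.85 (SE 0.20, 0.143), -0.60 (SE 0.16, 0.179) and -0.58 (SE 0.13, 0.122), and the p53 targets Eda2r and Trp53inp1 had 1.01 (SE 0.19, 0.0649) and 0.69 (SE 0.14, 0.0997).

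With each library's trend with transcript length removed, edgeR called 29 genes in OPCs and 166 in OLs. In OPCs these held the p53 targets Cdkn1a (0.51, adjusted p = 0.0300), Pmaip1 (0.87), Ercc5 (0.64) and Dcxr (0.67), the SRF targets Cnn2 (-1.46), Lima1, Egr1 and Egr2 (-1.65), and the astrocyte genes Id3 (0.73) and Clu (0.56). In OLs they held 6 p53 targets (Btg2, Ak1, Trp53inp1, Eda2r, Ephx1 and Dcxr), all higher. They also held 7 newly formed oligodendrocyte genes and 4 myelin genes, all lower, with Sirt2 counted in both lists, and Actb (-1.17, SE 0.235, adjusted p = 0.0432). The p53 list had a median of 0.27 in OPCs and 0.34 in OLs in these fits, and the SRF-MRTF list -0.22 and -0.20. Other called lists moved closer to 0 in edgeR medians: in OPCs mitochondrial genes from 0.20 to 0.08, focal adhesion from -0.09 to -0.04, OPC genes from -0.11 to -0.07 and fatty acid genes from -0.12 to -0.08, and in OLs senescence genes from 0.13 to 0.08. Without that removal the edgeR adjusted p of Actb was 0.187 in OPCs and 0.154 in OLs.

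The camera direction of a list and its median had opposite signs for tubulins, YAP-TEAD targets and sex-linked genes in OPCs and for Arp2/3, YAP-TEAD and integrated stress response genes in OLs, none of them called. Of 22 SRF-MRTF targets tested in both stages, 6 in OPCs and 3 in OLs were lower when adjusted over the list alone, 2 in both (Cnn2 and Actb), where 0.818 would be shared by independent sets (Fisher's exact p = 0.169).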
